A study of Mus musculus with 6 samples.

How the data were processed

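Gene expression was measured by RNA sequencing in 6 libraries from sorted lymph node T cells of C3H/HeJ mice. Both sorted populations carried CD3, CD8, CD44 and CXCR3 on their surface and differed in NKG2D, an activating receptor encoded by Klrk1. There were 3 NKG2D+ and 3 NKG2D- libraries. RNA was extracted on columns with DNase digestion and made into indexed TruSeq libraries, per the labels' protocols.

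The deposited values are read counts per gene symbol, 1 file per library, and the authors left them without normalisation. CASAVA 1.8.2, TopHat2 2.0.4 and the mm9 mouse genome are named in the submitters' processing notes. The counting program, its gene annotation and its strand setting are not given in the sources used here. Each deposited file holds counts for 23284 genes and 5 summary counts of reads that name no gene. Summary counts were left out of library sizes and tests. Reads outside annotated genes made up 14.01% to 15.87% of all counted reads, and reads overlapping more than 1 gene 0.715% to 0.836%. Reads aligned to several places made up 19.71% to 26.19%, and the counts of low quality and unaligned reads were 0 in every file. Because such reads were set aside, counts of genes with near-identical copies rest on the reads that could be placed, and those of overlapping or antisense genes depend on a strand setting that is not known. The reference table at hand is of assembly GRCm38, not mm9, so no coordinates are given and it served only to find neighbouring genes.

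Libraries were grouped by the labels, which number the replicates 1 to 3 in each population. The series description says that the populations came from 3 separate mice, so same-numbered libraries were taken to share a mouse. The names of the files give same-numbered libraries the same lane tag as well, so mouse and lane cannot be told apart. Deviations of log2 CPM from the group means correlated across genes between same-numbered libraries, with r = 0.21, 0.16 and 0.28, where genes are not independent replicates. It was over 0.1 in all 3 pairs and lay between -0.17 and 0.02 in the 6 pairs with different numbers across the populations. Taking deviations from group means makes a library's covariances with the other population cancel out. Low values in the pairs with different numbers are thus not separate evidence of the pairing. Libraries of 1 group differed by a chi-square of 40.7 to 235 per degree of freedom, so no library was a copy of another.

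Counts were tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16, with TMM normalisation, robust dispersion and robust quasi-likelihood fits (legacy mode), and group as the only term. Genes were kept by filterByExpr at its defaults, a minimum count of 10 and a minimum total of 15, which left 12951 genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values were computed with TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The standard error of a log2 fold change is its size divided by the square root of F. Klrk1 was also compared by a two-sided exact permutation test, whose lowest possible p is 0.1 for 3 against 3.

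Before the data were examined, 27 gene lists were fixed, covering NK-cell receptors, cytotoxicity, cytokines, effector transcription factors, naive and memory genes, inhibitory receptors, costimulation, cell cycle, homing, tissue residency, cytokine receptors, interferon response, glycolysis, NKG2D ligands, the T-cell receptor complex, immediate-early and heat-shock genes, ribosomal proteins, mitochondrially encoded genes and markers of 9 other kinds of cells. The 24 lists with at least 3 tested genes were compared two-sided with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Estimated correlations and fry were run beside it. The mitochondrial list matched no gene in the files.

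Named genes followed a rule fixed at the same time. It takes the genes of the sort markers, the 10 largest positive and the 10 largest negative log2 fold changes past the threshold with a mean of at least 5 CPM in the higher group and the same direction in all 3 pairs, and up to 4 called members of each list by smallest p. Where no member of a list passed, the member with the smallest p is given as a value only. Other genes are marked as chosen after their values were seen. A gene that this rule takes is not reported here.

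On simulated counts for the same comparison and 12951 genes, the test recovered 36% of 50 genes changed 1.5-fold, 70% of 50 changed 2-fold, 96% of 50 changed 4-fold and 100% of 50 changed 8-fold. It made 164 calls there, of which 13 were false. All 5 simulated lists of 20 genes raised 1.5-fold were called, and 0 of 20 unchanged lists. These simulated genes were independent of each other, with a dispersion set by expression, equal in both groups, and no difference between mice. In the data the spread could be wider in NKG2D+, as for Id2 (494 ± 321 against 70.3 ± 12.1 CPM). Xcr1, with a log2 fold change of 2.05, did not pass in edgeR (adjusted p = 0.0707). Recovery in the data may thus be lower than in the simulation.

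Alternatives fixed beforehand were a term for the replicate number, other size factors (RLE and upper quartile), no filter, a filter of 5 CPM in 3 libraries, each library or mouse left out, DESeq2 1.42.0 with and without the replicate number, limma-voom, the newer edgeR mode, a minimum log2 fold change of 1, an adjusted p under 0.01, list tests with estimated correlation or fry, lists without Klrk1, and Klrk1 without TMM factors. After seeing the data, a variance per group in limma-voom, an adjusted p under 0.1 and a B-cell marker score (the mean log2 CPM of 14 B-cell markers) as a covariate were added.

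Gene counts per library ran from 41168816 to 89184611. A floor of 3 counts corresponded to 0.034 to 0.073 CPM, and covers counting error only.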

Results

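CD8 T cells of the lymph node were sorted from C3H/HeJ mice, an inbred strain used as a model of the autoimmune hair loss disease alopecia areata. Whether these mice had the disease is not given in the sources used here. All sorted cells were CD3+CD8+CD44+CXCR3+, a surface phenotype of antigen-experienced T cells, and were parted into NKG2D+ and NKG2D- cells. RNA sequencing gave 63232698, 89184611 and 73989561 gene counts in the NKG2D+ libraries 1, 2 and 3, and 41168816, 59235219 and 67315805 in the NKG2D- libraries 1, 2 and 3. The ranges of the populations overlapped (two-sided exact permutation p = 0.2, n = 3 per group), but the NKG2D+ library was the deeper in all 3 same-numbered pairs (exact paired permutation p = 0.25, the lowest that 3 pairs allow). The share of reads aligned to several places was 20.32% ± 0.626 in NKG2D+ and 24.03% ± 2.33 in NKG2D- libraries (SD, n = 3, exact permutation p = 0.1, the lowest this design allows). NKG2D+ libraries had 16290 ± 212 genes detected against 15630 ± 404, and the 20 most abundant genes held 8.23% ± 0.78 against 11.09% ± 2.22 of their gene counts (SD, n = 3, exact permutation p = 0.1 for each). These 3 measures also differed in the same direction in all 3 pairs (exact paired permutation p = 0.25 for each). A gene was detected with at least 1 count, without matching depth. Detection rose with depth within each population, so its difference cannot be told apart from that of depth.

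The first comparison asked whether the RNA of the sort marker followed the sort. Klrk1, which encodes NKG2D, stood at 354 ± 49.7 CPM in NKG2D+ and 35.9 ± 1.35 CPM in NKG2D- cells (mean ± SD, n = 3 each). It was 9.86-fold higher in NKG2D+ cells, with a log2 fold change of 3.30 (SE 0.12) and an adjusted p of 0.000185 by edgeR's quasi-likelihood test. All 3 pairs showed the difference, and the two-sided exact permutation test gave p = 0.1, the lowest possible with 3 against 3. The NKG2D- libraries held 10.1% of the NKG2D+ level, and counts do not tell low expression from NKG2D+ cells left in the sort. Left-over cells with the average NKG2D+ profile would leave at least a like share of every gene. Gzma, Ifitm1 and Tjp1 stood in NKG2D- at 0.0193, 0.0209 and 0.0254 times their NKG2D+ level, lower shares than for Klrk1. These genes were picked for their large difference, and left-over cells with another profile stay open. With both libraries of mouse 3 left out, the log2 fold change was 3.33 and the adjusted p 0.105.

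By edgeR on all 6 libraries, the genes of the shared gate did not pass the test, although Cd44 passed without NKG2D+ library 1 or 2. Cd3e, a chain of the T-cell receptor complex, stood at 452 ± 46.1 against 428 ± 34.4 CPM (log2 fold change 0.08, SE 0.10, adjusted p = 0.71). Of the CD8 chains, Cd8a had a log2 fold change of 0.23 (adjusted p = 0.574) and Cd8b1 of -0.08 (adjusted p = 0.852). Cxcr3, a chemokine receptor, had a log2 fold change of 0.19 (adjusted p = 0.448). Cd44, an adhesion receptor that marks activated T cells, stood at 277 ± 135 CPM in NKG2D+ and 135 ± 2.1 CPM in NKG2D- cells. Its log2 fold change was 1.03 (SE 0.31) and its adjusted p 0.13, with 430 CPM in NKG2D+ library 1 against 177 and 224 CPM in libraries 2 and 3. Without NKG2D+ library 1 the log2 fold change of Cd44 was 0.57 (adjusted p = 0.0245) and without NKG2D+ library 2 1.27 (adjusted p = 0.0376), and DESeq2 gave an adjusted p of 0.00508.

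**Figure D1:**
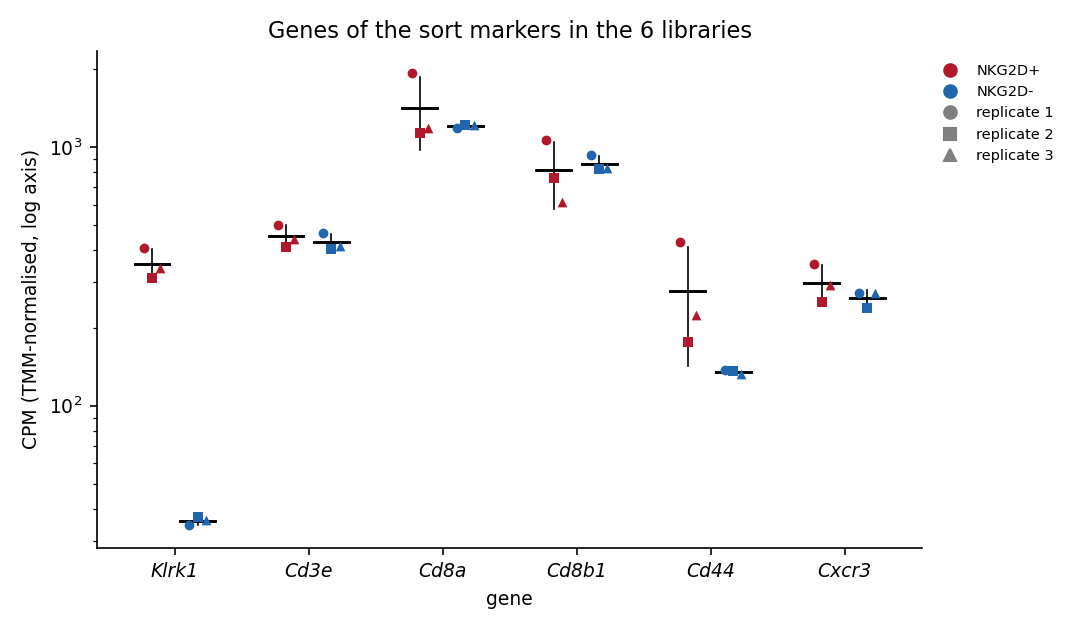
CPM (log axis) of the genes of the sort markers in each library, with NKG2D+ in red and NKG2D- in blue, a marker shape per replicate number, horizontal lines for the mean and vertical lines for 1 SD (n = 3). Klrk1 lies near 354 CPM in NKG2D+ and near 35.9 CPM in NKG2D- cells, while the other genes overlap or, for Cd44, spread widely in NKG2D+ cells.

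The second comparison asked which genes differed between NKG2D+ and NKG2D- cells. NKG2D+ cells expressed more of the granule protease gene Gzma, the interferon-induced membrane protein gene Ifitm1, the fractalkine receptor gene Cx3cr1 and the cytokine gene Csf1, by 51.7, 47.8, 47.7 and 34.7 times. The log2 fold change of Cx3cr1 rested in part on NKG2D+ library 1, at 5.58 with it and 4.59 without it. NKG2D- cells expressed more of Nrg2, Atp1b1 and Igfbp4, by 5.74, 5.06 and 3.65 times. Of 12951 genes tested, 214 were higher and 47 lower in NKG2D+ cells at an adjusted p under 0.05. Among them, 112 were at least 4-fold higher and 10 at least 4-fold lower. All 261 had the same direction in the 3 same-numbered pairs.

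The 10 largest increases began with Gstm5, a glutathione transferase, at 7.46 ± 4.74 against 0.0992 ± 0.0889 CPM (log2 fold change 6.22, SE 0.98, adjusted p = 0.0364). This gene had 5, 0 and 11 counts in NKG2D- libraries 1, 2 and 3. Gzma stood at 185 ± 112 against 3.49 ± 2.07 CPM (log2 fold change 5.69, SE 0.70, adjusted p = 0.022). Ifitm1 stood at 52.7 ± 21.6 against 1.13 ± 0.363 CPM, and Cx3cr1 at 67.9, 10.8 and 23.4 CPM in NKG2D+ libraries 1, 2 and 3 against 0.745 ± 0.442 CPM, both with a log2 fold change of 5.58 (SE 0.43 and 0.84). Tjp1, which encodes the tight junction protein ZO-1, followed at 5.30 (SE 0.45), then Metrnl at 5.22, the chemerin receptor gene Cmklr1 at 5.20, Epdr1 at 5.19, Csf1 at 5.11 and the chemokine receptor gene Ccr1 at 5.01. Without NKG2D+ library 1 Metrnl stood at 4.34, Epdr1 at 4.49 and Cx3cr1 at 4.59, and Gstm5 at 5.59 without NKG2D- library 2 (adjusted p = 0.126) and 7.09 without NKG2D- library 3 (adjusted p = 0.195), so the order of these genes depends on single libraries. Adjusted p-values of these 10 genes ran from 0.00714 for Ifitm1 to 0.0386 for Csf1. Ifitm1 has near relatives in the genome that can share reads, so its level is uncertain.

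The decreases were smaller. Nrg2, a neuregulin gene, stood at 2.71 ± 0.931 CPM in NKG2D+ and 15.6 ± 1.09 CPM in NKG2D- cells (log2 fold change -2.52, SE 0.26, adjusted p = 0.0153). Atp1b1, a subunit of the sodium pump, stood at 7.47 ± 1.27 against 37.8 ± 5.08 CPM (log2 fold change -2.34, SE 0.16, adjusted p = 0.00451). C85492 had a log2 fold change of -2.20, Lrrc3b of -2.07, Igfbp4, an insulin-like growth factor binding protein, of -1.87, and the alkaline phosphatase gene Alpl of -1.75. Eng, which encodes the TGF-beta co-receptor endoglin, followed at -1.64, the potassium channel gene Kcnf1 at -1.41, and Plac8 and Nacc2 at -1.37. Adjusted p-values ran from 0.00277 for Plac8 to 0.0491 for Nacc2.

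The replicate number as a block left 57 genes higher and 11 lower, and 57 of these 68 were among the 261. The blocked adjusted p was under 0.05 for all 10 increases above, while among the decreases it was 0.0558 for Nrg2 and Lrrc3b, 0.0677 for Eng and C85492 and 0.0963 for Nacc2. The count moved with each library left out: 543 genes without NKG2D+ library 1, 1312 without library 2 and 15 without library 3, and 21, 13 and 8 without NKG2D- libraries 1, 2 and 3. Without both libraries of mouse 3 edgeR called 0 genes, with 971 at an unadjusted p under 0.05, and on all libraries DESeq2 called 1444 and limma-voom 83, which left 1 of the 10 largest increases. Without the filter on low counts 234 of 18245 genes passed, 203 of them among the 261. Adjusted p-values there were 0.068 for Gzma, 0.0903 for Cx3cr1, 0.106 for Csf1, 0.0782 for Gstm5, 0.0702 for Cmklr1, 0.0555 for Metrnl, 0.0528 for Epdr1, 0.0852 for Gzmb, 0.105 for Id2, 0.08 for Prdm1 and Havcr2, 0.0998 for Cd244, 0.107 for Cd101 and 0.109 for Cxcr6.

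NKG2D+ cells expressed more of several other NK-cell receptor genes. Of 23 tested NK-cell receptor and adaptor genes, 8 rose in NKG2D+ cells and 0 fell, and 13 rose when adjusted over the list alone, with Klrk1 counted each time. Besides Klrk1, Klrc1, which encodes the inhibitory receptor NKG2A, stood at 73.4 ± 13.3 against 12.4 ± 2.76 CPM (log2 fold change 2.56, SE 0.21, adjusted p = 0.00714). Klrc2, which encodes NKG2C, rose by 2.27 (SE 0.18) and Klrd1, which encodes their partner chain CD94, by 1.01 (SE 0.11) on the log2 scale. The Klrc genes are close copies of each other, so their separate levels are uncertain. As a list these genes were higher by camera (adjusted p = 4.3e-27, and adjusted p = 0.041 with an estimated correlation). Both values include Klrk1, whose difference the sort fixed. Without Klrk1 the list kept its call with the preset correlation, and an estimated correlation was not tried without it.

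Of 17 tested genes of cytotoxic granules and death ligands, 3 rose and 0 fell, and 9 rose when adjusted over the list alone. They were Gzma, Gzmb, another granule protease, at 346 ± 203 against 17.6 ± 6.53 CPM (log2 fold change 4.30, SE 0.62, adjusted p = 0.0311), and Fasl, which encodes the death ligand FasL, at 45.8 ± 4.5 against 15.8 ± 3.03 CPM (log2 fold change 1.53, SE 0.15). Granzyme genes are related in sequence, so reads may have been lost or shared among them. The list was higher by camera (adjusted p = 2.6e-08, and adjusted p = 0.041 with an estimated correlation). These 2 lists alone held their call with an estimated correlation, the NK-cell receptor list with Klrk1 in it.

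When adjusted over all genes tested, a minority of the genes of cytokines, effector differentiation, inhibition and migration passed as higher. Their 4 lists lost their call with an estimated correlation. Of 16 cytokine and chemokine genes, 3 rose (11 when adjusted over the list alone): Ccl5, a chemokine gene, from 463 ± 26.1 to 1310 ± 353 CPM, Csf2, which encodes GM-CSF, from 0.428 ± 0.139 to 1.94 ± 0.277 CPM, and Csf1, which encodes M-CSF, from 9.14 ± 5.17 to 313 ± 221 CPM. The camera adjusted p was 2.4e-10, and adjusted p = 0.15 with an estimated correlation. Of 16 transcription factors of effector differentiation, 4 rose (10 when adjusted over the list alone): Id2 by 2.81, Zeb2 by 2.09, Prdm1, which encodes Blimp-1, by 2.01 and Bhlhe40 by 1.26 on the log2 scale. These were higher by camera (adjusted p = 4.4e-07), with adjusted p = 0.18 with an estimated correlation. Under the block 1 of the cytokine genes and 0 of the transcription factors passed, with adjusted p-values of 0.0836 for Id2, 0.0931 for Zeb2, 0.104 for Prdm1, 0.0558 for Bhlhe40, 0.0597 for Ccl5 and 0.0696 for Csf2. Id2 stood at 2.18 without NKG2D+ library 1.

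Of 19 inhibitory receptor and dysfunction genes, 3 rose: Havcr2, which encodes TIM-3, by 4.43, Cd244, which encodes 2B4, by 5.01 and Cd101 by 2.33 on the log2 scale (blocked adjusted p = 0.107 for Cd101). Cd244 stood at 4.06 without NKG2D+ library 1 and at 5.68 without NKG2D- library 1 (adjusted p = 0.157). When adjusted over the list alone, 7 rose and 1 fell. The list was higher by camera (adjusted p = 0.00018), and adjusted p = 0.32 with an estimated correlation. Of 31 genes of chemokine receptors, integrins and selectin-ligand enzymes, 8 rose and 1 fell, and 15 rose and 2 fell when adjusted over the list alone. Itga1, which encodes the collagen-binding integrin chain CD49a, stood at 184 ± 106 against 9.21 ± 0.822 CPM (log2 fold change 4.32), and Itga2, which encodes CD49b, rose by 1.48. Cxcr5, a receptor for follicular homing, fell by 0.66 on the log2 scale. For homing genes camera gave an adjusted p of 8.9e-14, and adjusted p = 0.15 with an estimated correlation.

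Of 18 genes of tissue-resident memory T cells, 3 rose: Itga1, the E-cadherin gene Cdh1 by 3.08 and the chemokine receptor gene Cxcr6 by 2.27 on the log2 scale. When adjusted over the list alone, 10 rose and 1 fell. By camera the residency list was higher (adjusted p = 2.8e-08), and adjusted p = 0.20 with an estimated correlation. With the replicate block, 3 homing genes and 1 residency gene passed, with adjusted p-values of 0.0537 for Itga1, 0.0677 for Itga2, 0.0518 for Cxcr5 and 0.0909 for Cxcr6.

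Summed markers of B cells, myeloid cells, gamma-delta and NKT cells and plasma cells were higher in every NKG2D+ library than in every NKG2D- library. All but the plasma cell list were called by camera, beside these lists and the cell-cycle, naive and ribosomal protein lists. The summed CPM of 14 B-cell marker genes was 682, 425 and 479 in NKG2D+ and 119, 314 and 261 in NKG2D- libraries 1, 2 and 3. Without Cd22, the sum was 536, 226 and 272 against 60.5, 201 and 146. That of 21 myeloid markers was 1370, 603 and 692 against 294, 574 and 434, and that of 6 gamma-delta and NKT cell markers 302, 144 and 176 against 63.7, 54.6 and 55.8. For 6 plasma cell markers it was 86.9, 42.6 and 59.4 against 40.5, 37.9 and 39.3. These sums are not separate signs of each cell type. Blk is in both the B-cell and the gamma-delta list. The myeloid list holds the MHC class II pathway genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74, which B cells express too. Their log2 fold changes were 1.34 to 1.45, and these 5 genes were named after their values were seen. All 14 B-cell markers had a positive log2 fold change, with a median of 1.41. By edgeR 0 of them passed, with 12 at an unadjusted p under 0.05, and 0 when adjusted over the list alone, and DESeq2 called 3 and limma-voom 0. Cd22, the member with the smallest p, stood at 185 ± 32.8 against 95.3 ± 32.4 CPM (adjusted p = 0.123). Camera called the list (adjusted p = 1.8e-07), and the adjusted p was 0.32 with an estimated correlation of 0.82. With the mean log2 CPM of these markers as a covariate, added after seeing the data, edgeR called 2 genes, Klrk1 and Ifitm1, in place of 261. All 261 kept their direction, with a median of 0.809 times the log2 fold change (quartiles 0.723 and 0.936), a median SE of 0.33 in place of 0.26 and 3 residual degrees of freedom in place of 4. Under the covariate Gzma stood at 5.76 (SE 1.06, against 5.69 and 0.70), Csf1 at 5.27 (SE 1.56, against 5.11 and 0.83), Mki67 at 1.08 (SE 0.17, against 1.12 and 0.10) and Cd101 at 1.32 (SE 0.45, against 2.33 and 0.41).

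**Figure D2:**
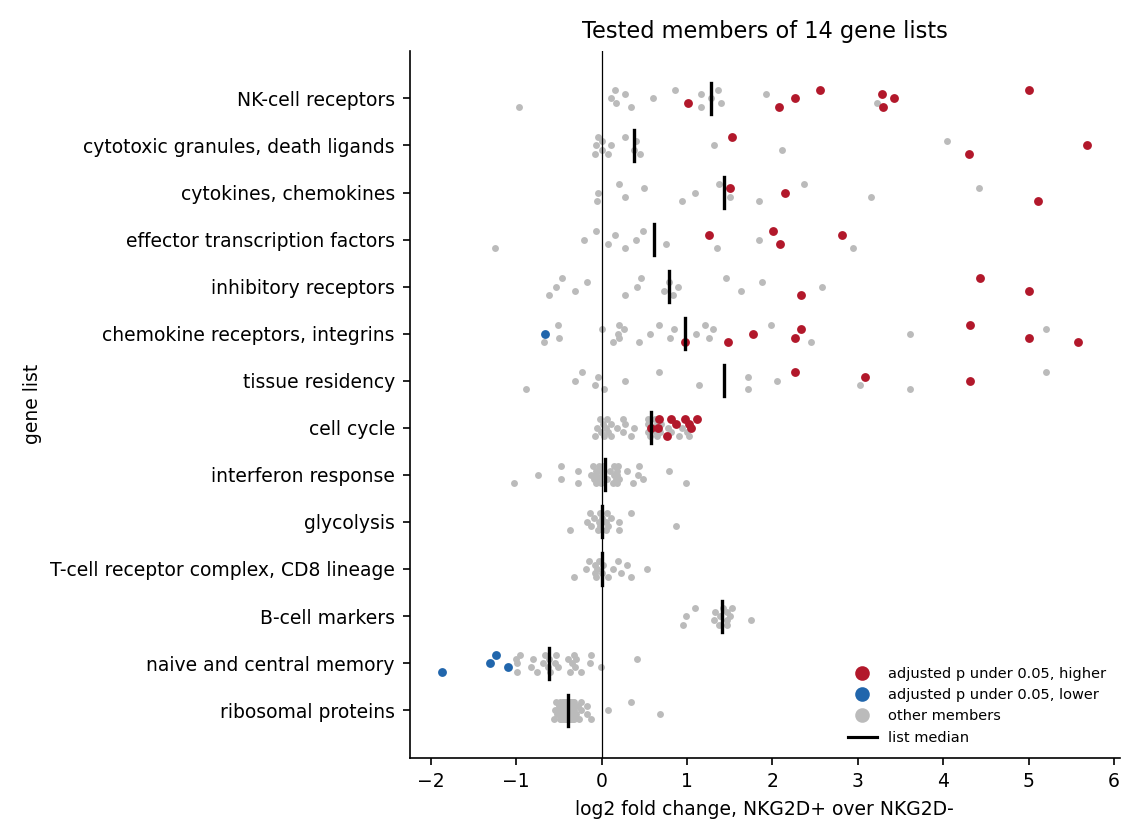
Log2 fold changes (NKG2D+ over NKG2D-) of the tested members of 14 of the gene lists, with members past the adjusted p threshold in red (higher) or blue (lower), other members in grey and the list median as a black line. The median was 1.28 for NK-cell receptors, 0.04 for the interferon response, 1.41 for B-cell markers and -0.61 for naive and central memory genes.

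Some cell-cycle genes were higher in NKG2D+ cells. Of 43 tested, 10 rose and 0 fell, and 25 rose when adjusted over the list alone. Mki67, which encodes the proliferation antigen Ki-67, stood at 85.7 ± 8.68 against 39.5 ± 3.03 CPM (log2 fold change 1.12, SE 0.10, adjusted p = 0.0089). Top2a, a topoisomerase of dividing cells, stood at 63.5 ± 2.29 against 34.9 ± 2.49 CPM. The mitotic kinesin gene Kif11 rose by 0.98 and Stmn1, which encodes the microtubule regulator stathmin, by 0.58 on the log2 scale. The list was higher by camera (adjusted p = 5.9e-15, and adjusted p = 0.12 with an estimated correlation) and by fry (adjusted p = 0.0039). With the replicate block 3 of the 43 genes passed, Mki67, Top2a and Rrm2, and the adjusted p was 0.0558 for Kif11 and 0.0687 for Stmn1.

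Some genes of naive and central memory T cells were lower. Of 30 tested, 4 fell and 0 rose, and 18 fell when adjusted over the list alone. Igfbp4 stood at 20.9 ± 4.22 in NKG2D+ against 76.3 ± 16.4 CPM in NKG2D- cells, Dapl1 at 25.5 ± 2.55 against 59.7 ± 3.24 CPM, and Actn1, which encodes an alpha-actinin, at 158 ± 14.8 against 390 ± 74.4 CPM. Id3, a regulator of transcription, fell by 1.09 on the log2 scale (SE 0.20, adjusted p = 0.0498). By camera the list was lower (adjusted p = 5e-20, and adjusted p = 0.15 with an estimated correlation), and by fry as well (adjusted p = 0.039). The blocked adjusted p was 0.0539 for Actn1.

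Ribosomal protein genes gave a list call, while edgeR called none of them and DESeq2 40. Of 79 tested, 76 had a negative log2 fold change, with a median of -0.39. By edgeR 0 passed over all genes, with 67 at an unadjusted p under 0.05, and 62 were lower when adjusted over the list alone, while limma-voom called 0. Camera gave an adjusted p of 2.2e-24, and adjusted p = 0.30 with an estimated correlation of 0.72. Ribosomal protein genes have many processed copies, so their levels are uncertain.

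**Figure D3:**
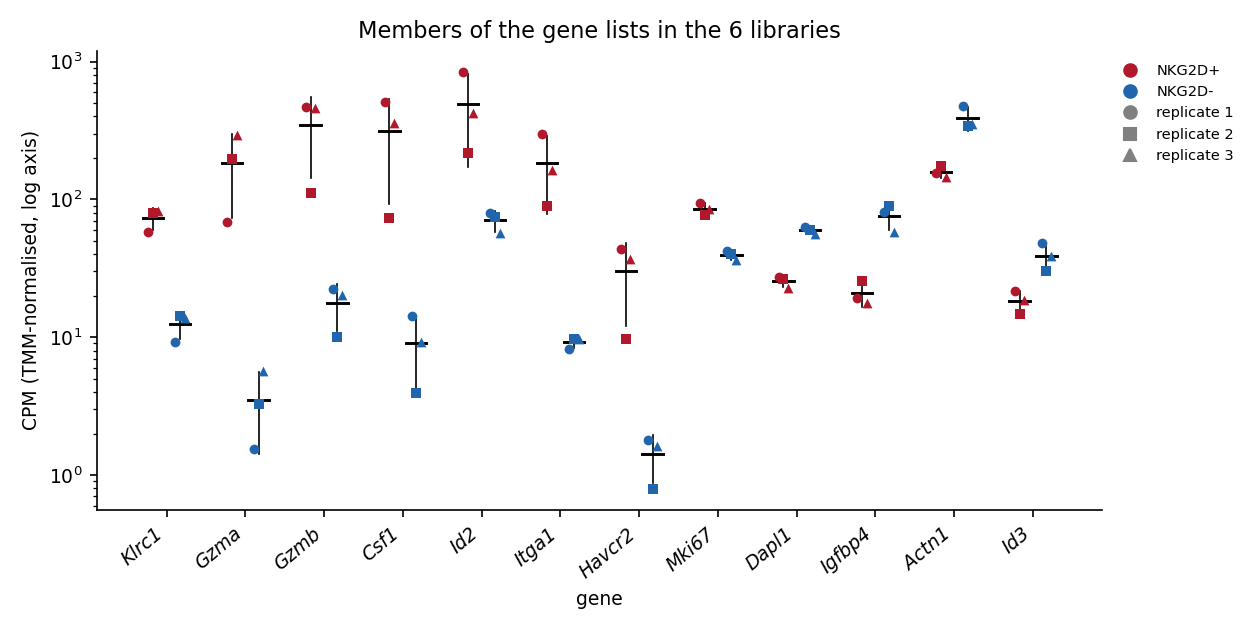
CPM (log axis) of 12 called list members in each library, with NKG2D+ in red and NKG2D- in blue, a marker shape per replicate number, horizontal lines for the mean and vertical lines for 1 SD (n = 3). Gzma has means of 185 and 3.49 CPM and Id2 means of 494 and 70.3 CPM, while Dapl1, Igfbp4, Actn1 and Id3 are lower in NKG2D+ cells.

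Lists of interferon-stimulated, glycolysis, T-cell receptor and immediate-early genes were not called. Of 36 interferon-stimulated genes 0 passed by edgeR, over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05, and DESeq2 called 4 and limma-voom 0 (camera adjusted p = 0.88, median log2 fold change 0.04). Ifi44 had a log2 fold change of -0.74 (adjusted p = 0.0921), and the replicate block called 1 gene of the list, Oas2. Of 19 glycolysis genes edgeR called 0, with 4 at an unadjusted p under 0.05, DESeq2 1 and limma-voom 0 (camera adjusted p = 0.88), with Slc16a3 at 0.87 (adjusted p = 0.132, and 0.0477 without NKG2D+ library 2). Of 17 genes of the T-cell receptor complex and CD8 lineage edgeR called 0, with 2 at an unadjusted p under 0.05, DESeq2 1 and limma-voom 0 (camera adjusted p = 0.88), with Thy1 at 0.35 (adjusted p = 0.126, and 0.0354 without NKG2D+ library 2). Of 22 immediate-early and heat-shock genes edgeR, DESeq2 and limma-voom each called 0, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.60), and Ier3 stood at 0.36 (adjusted p = 0.313). That list was called without NKG2D+ library 3 (adjusted p = 0.0317) and without NKG2D- library 1 (adjusted p = 0.0133). Adjusted over the list alone, 0 genes passed in these last 3 lists.

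Costimulation genes went both ways. Of 19 tested, Cd38 rose by 0.83 and the TNF receptor gene Tnfrsf1b by 0.49, and Tnfrsf25, another TNF receptor family gene, fell by 1.07 on the log2 scale. When adjusted over the list alone, 6 rose and 4 fell (camera adjusted p = 0.23, and 0.0127 without NKG2D+ library 2). Of 39 cytokine receptor and JAK-STAT genes, the signalling inhibitor gene Socs2 rose by 2.26 and the interleukin receptor gene Il4ra fell by 0.57. When adjusted over the list alone, 7 rose and 3 fell (camera adjusted p = 0.23). In the blocked fit these 5 genes had adjusted p-values of 0.053, 0.102, 0.0677, 0.0806 and 0.0554 in the order named, and Slamf7 was called (adjusted p = 0.0472). Of the NKG2D ligand genes only H60b was tested, at 0.334 ± 0.136 against 0.449 ± 0.287 CPM (adjusted p = 0.733), and strain differences from the reference can hide such ligands.

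Markers of other cells were counted as well. Of 21 macrophage, monocyte and dendritic cell markers edgeR called 0, with 13 at an unadjusted p under 0.05 and 1 higher when adjusted over the list alone, DESeq2 2 and limma-voom 0. The list was higher by camera (camera adjusted p = 0.0021, adjusted p = 0.0928 without mouse 1, and adjusted p = 0.43 with an estimated correlation), with Xcr1 at 2.05 (adjusted p = 0.0707, and 0.0452 and 0.00379 without NKG2D+ library 1 or 2). Its members disagreed, with 16 positive and 5 negative log2 fold changes. Clec9a stood at -1.55 and Siglech at -1.21, both uncalled and chosen after their values were seen. Under the B-cell covariate the direction of this list turned (camera adjusted p = 0.795). Of 6 gamma-delta and NKT cell markers edgeR called 0, with 5 at an unadjusted p under 0.05 and 2 higher when adjusted over the list alone, DESeq2 2 and limma-voom 0. This list was also higher by camera (camera adjusted p = 0.00053, and adjusted p = 0.12 with an estimated correlation), with Cd163l1 at 1.13 (adjusted p = 0.0538, and 0.0321 and 0.00629 without NKG2D+ library 1 or 2). Of 10 NK-cell markers, Itga2 and Styk1, a kinase gene, rose, the latter by 3.43 on the log2 scale (4.14 without NKG2D- library 3), and 4 rose when adjusted over the list alone (camera adjusted p = 6.5e-06, and adjusted p = 0.15 with an estimated correlation). Their summed CPM was 178, 384 and 308 in NKG2D+ and 299, 299 and 320 in NKG2D- libraries 1, 2 and 3, lowest in NKG2D+ library 1. Of 6 plasma cell markers edgeR called 0, also when adjusted over the list alone, with 1 at an unadjusted p under 0.05, DESeq2 1 and limma-voom 0 (camera adjusted p = 0.078, and 0.0446 without NKG2D- library 3), with Xbp1 at 0.69 (adjusted p = 0.186, and 0.032 without NKG2D+ library 2).

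Of 3 neutrophil markers edgeR, DESeq2 and limma-voom each called 0, edgeR also when adjusted over the list alone, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.88, and 0.00345 without NKG2D+ library 3), with S100a9 at 1.10 (adjusted p = 0.465). Over the alternative fits the log2 fold change of S100a9 ran from -0.39 to 1.58. Of 7 CD4 and regulatory T-cell markers edgeR called 0, with 5 at an unadjusted p under 0.05, DESeq2 5 and limma-voom 0, and 2 were higher and 3 lower when adjusted over the list alone. Their mean log2 fold change was 0.23 and their median -0.07, camera's direction was down (adjusted p = 0.62), and Foxp3 stood at 4.88 ± 2.41 against 17.1 ± 3.32 CPM (adjusted p = 0.0687, and 0.0217 and 0.0127 without NKG2D+ library 1 or 2). Of 4 stroma and skin markers the collagen gene Col1a1 rose by 1.42 and Pecam1 fell by 0.47 on the log2 scale (blocked adjusted p = 0.0806 and 0.0537), and 2 were higher and 2 lower when adjusted over the list alone. The list's median was 0.34 and camera's direction down (adjusted p = 0.88). Only 2 red cell and platelet markers were tested, with Itga2b at -0.20 (adjusted p = 0.711).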

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

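These values come from the summary counts of reads that no gene comparison uses, and no test of them was chosen after the result was seen. Reads aligned to several places made up a median of 21.3% of all counted reads over the 6 libraries, and are given as a signal outside the gene comparisons, with no control libraries to set them against. Reads outside annotated genes made up a median of 14.4%, and reads that overlapped more than 1 gene a median of 0.79%. No explanation of these shares was tested, biological or technical.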

How the results depend on the processing

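The B-cell covariate, the variance per group and the threshold of 0.1 were chosen after seeing the data. Numbers of genes within 1.5 times the 261 came from edgeR with RLE (246) or upper-quartile factors (270), without a filter (234), in its newer mode (197) and with a log2 minimum of 1 (192), and from limma-voom with a variance per group (220). With the replicate block 68 genes passed (57 higher, 11 lower), with the stricter filter, which tests fewer genes, 152 (125 and 27), and with limma-voom 83 (60 and 23). An adjusted p under 0.01 left 15 (11 and 4) and under 0.1 860 (645 and 215). DESeq2 gave 1444 (1028 and 416), and with the block 1776 (1075 and 701). The B-cell covariate left 2 (2 and 0), with 553 at an unadjusted p under 0.05, while all 261 kept their direction at a median of 0.809 times the log2 fold change, with a median SE of 0.33 in place of 0.26 and 3 residual degrees of freedom in place of 4. Summed B-cell CPM was higher in all NKG2D+ than in all NKG2D- libraries. Leaving out 1 library gave 8 to 1312 genes (4 to 904 higher, 4 to 408 lower), with 1312 without NKG2D+ library 2 and 543 without library 1. Without mouse 1, 2 or 3 edgeR called 229, 354 and 0 genes (0 and 0 by direction without mouse 3, with 971 at an unadjusted p under 0.05). Of the 261 genes 147 and 181 stayed called without mouse 1 and 2. Of 54 named genes with a call, Klrk1 aside, 15 and 11 lost it there, with 5 and 1 of the 10 largest increases among them. Fewer libraries leave fewer residual degrees of freedom, and for the rises and all other differences the cause was not tested. Klrk1 had log2 fold changes of 3.09 to 3.42 over its alternatives (3.19 to 3.39 without 1 library) and lost its call once, without mouse 3 (3.33, adjusted p = 0.105). Of 24 lists 14 were called with the preset correlation, 2 with an estimated correlation, 6 with fry and 13 to 16 when a library or mouse was left out. Fry called NK-cell receptors, cytotoxicity and cell cycle (adjusted p = 0.0039 each), naive and memory genes (0.039), and gamma-delta and NKT cell markers and NK-cell markers (0.023 each). Left-out mice also brought calls of costimulation (0.0225 without mouse 2), plasma cell (0.0494 and 0.0443 without mouse 2 and 3) and neutrophil lists (0.0024 without mouse 3). Of the named genes other than Klrk1, 5, 0 and 46 lost their call without NKG2D+ libraries 1, 2 and 3, and 44, 48 and 49 without NKG2D- libraries 1, 2 and 3. Of the 54 of them with a call the block ended 26 calls, no filter 14, the stricter filter 15, genes it no longer tests included, RLE 2, upper-quartile factors 1, the newer mode 9, limma-voom 25, a variance per group 11 and DESeq2 0. Of the 261 genes 203 stayed called without a filter, 245 with RLE, 256 with upper-quartile factors, 195 in the newer mode and 202 with a variance per group. In the order of the libraries 4, 8, 0, 0, 0 and 0 gained one, Cd44, Foxp3, Cd163l1 and Xcr1 both without NKG2D+ library 1 and without library 2, and DESeq2 brought 10. The replicate block changed no list call and, among the named genes, no call beyond those printed beside them.

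Directions turned only for genes and lists without a call, and for B-cell and myeloid markers under the B-cell covariate. Over the fits without 1 library the log2 fold change ran from -0.06 to 0.37 for Cd8a, 0.00 to 0.14 for Cd3e, -0.33 to 0.09 for Cd8b1, -0.66 to 0.23 for H60b and -0.40 to 0.03 for Itga2b. Without mouse 1 it was -0.08 for Cd8a and 0.04 for Itga2b, and without mouse 3 0.06 for Cd8b1. With the B-cell covariate it was -0.13 for Cd8a, 0.14 for Itga2b, -0.39 for S100a9 and 0.44 for H60b. Over the fits without 1 library the list adjusted p ran from 0.136 to 0.9 for the interferon response, 0.446 to 0.985 for the T-cell receptor complex, 0.0133 to 0.9 for immediate-early genes, 0.768 to 0.985 for glycolysis, 0.283 to 0.944 for CD4 markers, 0.00345 to 0.815 for neutrophil markers and 0.699 to 0.9 for stroma markers. Where they turned without mouse 1 it was 0.15 for the interferon response, 0.871 for the T-cell receptor complex and 0.989 for neutrophil and stroma markers, and without mouse 2 0.809 for glycolysis and CD4 markers. The interferon response turned with the block (0.955) and, under the B-cell covariate, turned and was called lower (0.0259). B-cell, myeloid and neutrophil markers turned under that covariate with 0.712, 0.795 and 0.911. Depth limits genes near 0.034 to 0.073 CPM, where a library holds 3 counts.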

Other observations

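Every test in this part was chosen after the result was seen, except the counts of other splits of the libraries. Of 17 tested semaphorin and plexin genes, which encode guidance cues and their receptors, 5 were higher in NKG2D+ cells and 0 lower: Plxnd1, Sema4a, Sema4c, Sema6b and Sema6d. Sema6d stood at 101 ± 89.6 against 3.78 ± 1.35 CPM (log2 fold change 4.76, adjusted p = 0.0391) and Sema4a at 809 ± 26.2 against 570 ± 59.4 CPM (SD, n = 3). Of 3 Ifitm genes, 2 were higher, Ifitm1 and Ifitm2. Of 9 annexin genes, 2 were higher: Anxa1 at 44.5 ± 37.2 against 2.71 ± 0.709 CPM, and Anxa2. Of 9 S100 genes, S100a4 was higher, at 291 ± 208 against 26.6 ± 4.72 CPM. With the replicate block the adjusted p was 0.0557 for Sema6d, 0.0945 for Sema4a, 0.0931 for Plxnd1, 0.053 for Sema4c, 0.0687 for Sema6b, 0.054 for Anxa2, 0.102 for Anxa1 and 0.0838 for S100a4. Leaving out NKG2D+ library 1 gave log2 fold changes of 3.80 for Sema6d (adjusted p = 0.0524, from 4.76), 3.16 for Anxa1 (adjusted p = 0.0514, from 4.04), 3.07 for Sema4c (from 3.75) and 2.74 for S100a4 (from 3.45).

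Among genes lower in NKG2D+ cells, also chosen after their values were seen, Lrrc32, which encodes the latent TGF-beta docking protein GARP of regulatory T cells, stood at 0.271 ± 0.152 against 2.72 ± 0.28 CPM (adjusted p = 0.0208). Dntt, which encodes the polymerase that adds nucleotides to receptor junctions in the thymus, stood at 0.183 ± 0.0695 against 1.13 ± 0.204 CPM (adjusted p = 0.0249). Blocked adjusted p-values were 0.0674 and 0.0537. Of the 11 genes called higher or lower here, counting Ifitm2 and not Ifitm1, 10 lost their call without NKG2D+ library 3 and all 11 without NKG2D- library 1, 2 or 3. Tigit, an inhibitory receptor gene, had an adjusted p of 0.0682 by edgeR, 0.0472 with the block, 0.0321 and 0.0158 without NKG2D+ library 1 or 2, 2.95e-06 by DESeq2 and 0.13 by limma-voom.

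There are 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 261 genes, as many as 1 of the 10 splits counting itself, and the highest of the others gave 0, where edgeR was the only tool run and 16 to 1068 genes had an unadjusted p under 0.05. It gave 14 lists, and 3 of the 10 splits, the real one included, gave as many, with 16 as the highest of the others. Of the 4 splits that part all 3 pairs, the other 3 gave at most 0 genes and 16 lists, and the splits that part 1 pair at most 0 genes and 15 lists. A split of other libraries thus gave more list calls with the preset correlation than the real one.

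NKG2D+ library 2 was lower than the other NKG2D+ libraries in most of the 214 genes called higher: 180 were higher in library 1 and 182 in library 3. NKG2D- cells in that sort, as the only source, would lower every gene's excess over NKG2D- by a common factor, and the ratio of library 2 to library 1 had a median of 0.479 (quartiles 0.278 and 0.805) and was above 1 for 15.9% of the genes, at 0.74 for Klrk1, 1.48 for Klrc1 and 2.98 for Gzma, which go against 1 common factor, but each mouse gave 1 library per population, so spread between mice leaves admixture open. B-cell RNA as the source for every gene is argued against in these libraries by 44 of 180 genes (24.4%, exact 95% binomial interval 18.4 to 31.4%). Their whole level in each NKG2D- library, scaled by the markers without Cd22, came to under 0.5 of the gap. Genes are not independent and all rest on the gap between NKG2D+ libraries 1 and 2, so the interval does not cover spread between mice. All 180 were picked as higher in NKG2D+, which favours a low NKG2D- level and so a low limit, and the share holds for such genes only. For the other 136 genes this limit had a median of 4.12 times the gap, and the difference between NKG2D- libraries 2 and 1 had a median of 0.192 and a 75th percentile of 0.55 of what the markers would give, where 0.5 or more was needed of the median, but between mice this leaves B-cell RNA open. A handling response stays open, as the immediate-early list had a median log2 ratio of -0.14 between libraries 3 and 2 with a spread that overlaps that of the called genes. Between libraries 1 and 2 the median of that list was 0.71, with 21 of 22 genes higher in library 1, against 0.62 for the called genes. Differences between mice were not tested.

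RNA from B cells is a candidate explanation of the B-cell markers, although the CD3 and CD8 gate would remove B cells. Centred within each group, each marker followed the rest of its list with a median correlation of 0.98 over the 6 libraries, against a 95th percentile of 0.58 for 10000 random lists matched on expression. The markers thus vary together within the populations. Other sets of genes that vary together could pass this comparison too, and centring removes the difference between the populations, so it does not settle the source. Cd79a stood at 105, 39.0 and 43.4 CPM in NKG2D+ and 9.02, 32.9 and 22.6 CPM in NKG2D- libraries 1, 2 and 3. Cd22 stood at 147, 200 and 207 against 58.0, 113 and 115 CPM: its log2 ratio of library 1 over the other 2 was -0.47 in NKG2D+, where the other markers lay between 0.74 and 1.56, and -0.98 in NKG2D-, within their -2.27 to -0.55, so 1 library keeps it open whether B-cell RNA accounts for Cd22. Whether the difference between the populations reflects the sort or the node was not tested.

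A few genes differed between same-numbered pairs of libraries in both populations. By a rule of at least 4-fold beyond all other libraries and a mean of at least 1 CPM on the higher side, 6 genes set a same-numbered pair apart, making 7 cases over the 3 pairs, and 0 did so in the 6 pairs with different numbers: Rpl3l stood at 16.1 and 24.5 CPM in the libraries of mouse 1 and at most 0.0469 CPM elsewhere, Shroom4 at 1.19 and 1.47 CPM in mouse 3 against 26.6 to 50.7 CPM, and the others were Gm12191, Mmp9, Hspa1a and Baiap2l1. Carry-over of reads between indexed libraries would leave under 10% of the higher level in the lower library. For the 5 genes higher in 1 mouse the lower library held at least 49.4%. The rule shut out a share under 10% for all of them except Rpl3l, because the lower library had to lie 4-fold above the others. For Rpl3l the lower library held 65.8%, which argues against carry-over for that gene alone. Tested neighbours of the genes other than Hspa1a and Mmp9, found on assembly GRCm38, differed by at most 0.19 log2 units in the same direction, which argues against reads running in, while Hspa1b beside Hspa1a, a near-identical copy, differed by 3.00 and Slc12a5 beside Mmp9 by 1.32. A shared lane in place of a shared animal cannot be told apart for these 7 cases, because each number has 1 lane, and a genetic difference between the mice was not tested. Hspa1a is in the immediate-early and heat-shock list. Relative to the mean of all 6 libraries, the median of that list was 0.65 and 0.38 log2 units in NKG2D+ and NKG2D- library 1. In the other libraries it was -0.25 to -0.1. A handling response of mouse 1 was not tested and stays open for Hspa1a.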
